A study of Bos taurus with 6 samples.

How the data were processed

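Blood from the jugular vein of 6 female cattle was profiled, 3 carrying the fat-1 transgene and 3 wild type, with 1 array per animal. The fat-1 gene of the nematode Caenorhabditis elegans encodes a desaturase that turns omega-6 into omega-3 polyunsaturated fatty acids, a step mammals lack. Per the labels, fat-1 replicate 1 was 3.5 years old and the other 5 animals were 3 years old. Total RNA was extracted with Trizol, cleaned on RNeasy columns and labelled with the dye Cy3 as cRNA, per the labels' protocols. Each array is a 1-colour Agilent bovine array with 43653 probes besides controls, most of them 60 bases long.

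The scanner files hold spot intensity made by Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and per the file headers. The processed intensity of a spot is background-subtracted and corrected for gradients across the slide, with a surrogate value close to background for the dimmest spots, per the file headers, and it is not scaled between arrays. The surrogate makes replicate spread at the dim end smaller than it would be for a plain subtraction. The raw mean and local background intensity of each spot were used, as deposited, in an alternative. Other columns used as deposited were flags of 0 or 1 for spots well above background, positive and significant, saturated or outlying. The authors' value table holds log2 values, as deposited, with the same distribution on every array. Each of its columns correlated with its own array at r of 0.999 or above over probes and with other arrays at 0.986 or below, so its rows were matched to probes, and it was read as log2 processed intensity after quantile normalization. The median of each column was 6.38. The tool that made the table is not given in the sources used here. The file of wild type replicate 2 had been saved again with values kept to 3 significant digits, against 7 in the others, and with 56 altered gene names, so all names were taken from the first file.

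Arrays of fat-1 animals shared slide 1 and scan 1, and those of wild type animals slide 2 and scan 2. Slide and group cannot be told apart, and the slide could not be fitted as a block. The number of arrays limits the precision. The share of probes well above background and the 75th percentile of intensity describe the signal of each array. Spike-in transcripts, 10 on each array, gave a further check.

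Processed intensity was taken to log2 and reduced by each array's 75th percentile over probes other than controls. Spots of a probe were averaged, and 32 probes with an outlier flag on some array were left out. Probes well above background on at least 3 of the 6 arrays, from whichever group, were kept, which left 26823 probes with 10768 gene symbols. Differences between the groups were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term and Benjamini-Hochberg adjustment over all probes kept. The threshold was an adjusted p of 0.05. A second count took probes at least 2-fold different at an unadjusted p under 0.05. Differences are fat-1 minus wild type on the log2 scale, with the standard error of the fit. Levels are log2 relative to the 75th percentile of the array, as mean and SD over 3 animals. Where a probe was not well above background on any array of a group, the fold is a bound. The bound holds for processed intensity only and has no error, and another background correction can give less. It compares the mean of the brighter group with the mean, over arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background on that array.

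Gene names came from the accession of each probe through a table of RefSeq genes of the assembly ARS-UCD2.0 for 20595 probes, from a symbol in that table for 10751 and from an older symbol for 406. Another 537 kept the file's own name, and 11364 had no symbol. Positions are those of the files, on the build Btau_3.1 per the file headers, and were available for 41544 probes. Exons and untranslated regions were not assigned, because no annotation of that build was used here. The genes named are the 10 with the highest and the 10 with the lowest difference among those past the threshold with a symbol and no overlap between the groups' animals, with unnamed loci passed over. Within lists that passed, and within the 7 lipid lists, up to 4 members with the smallest p that passed are named, or 2 as values where none did. Of other lists up to 2 members that passed are named. ACTB, GAPDH and PPIA are given as reference genes, and the transgene was to be given if a probe was annotated to it. Any other gene was chosen after its values were seen.

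In all, 30 gene lists were fixed from textbook knowledge, and each had at least 5 measured members, with 1 probe per gene, the brightest over all arrays. The lipid lists were PUFA (polyunsaturated fatty acid) desaturation and elongation, fatty acid and triglyceride synthesis, fatty acid oxidation, cholesterol synthesis, cholesterol efflux and LXR targets, lipid uptake, storage and lipolysis, and eicosanoid synthesis and receptors. Immune and stress lists covered inflammatory cytokines with the NF-kB response, the Toll-like receptor pathway, interferon-stimulated genes, class I and class II antigen presentation, antioxidant genes, and immediate-early and heat shock genes known to respond to blood handling. Further lists held oxidative phosphorylation, imprinted, proliferation and housekeeping genes. Marker lists stood for neutrophils, monocytes, alpha-beta and gamma-delta T cells, B cells, plasma cells, NK and cytotoxic cells, eosinophils, basophils and mast cells, erythroid cells, platelets and dendritic cells. Members were matched by current symbol, and by the file's own name where no probe carried the current one. This matching rule was set after the data were seen, because older names joined relatives such as OAS1X and OAS1Z. The lists were tested with camera of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were run beside it. Members were also tested with the p adjusted over the list alone.

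The share of probes well above background was compared by a two-sided exact permutation test, which with 3 animals against 3 cannot give a p below 0.1. The fit was tested on simulated data for fat-1 against wild type with 26823 probes, where it called 24% of probes changed 2-fold, 82% of those changed 4-fold, 96% at 8-fold and all at 16-fold, with 6.21% of calls on unchanged probes. The list test called the 1 shifted list and 0 of the other lists among 30 simulated ones. Probes were simulated independently of each other, so this does not show how often the list test errs when genes of a list are correlated. The alternatives were quantile scaling, scaling on the median of probes well above background on all arrays, normexp background correction with an offset of 50, the authors' value table, 3 other filters on dim probes, an intensity trend with robust variances, array weights, the replicate number as a block, an adjusted p of 0.1, the mean of all probes of a gene, and leaving out each array in turn. The normexp offset is added to every intensity and so draws log2 differences of dim probes towards 0 by construction. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, array weights used statmod 1.5.0, and plots used matplotlib 3.10.9. The submitters' PCR measurements were not used here.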

Results

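Transcript levels in whole blood were measured in 3 fat-1 transgenic and 3 wild type cows, to compare gene expression, and that of lipid metabolism in particular, between animals with and without the omega-3 desaturase. The 75th percentile of intensity was 715, 746 and 1068 on the fat-1 arrays and 743, 612 and 888 on the wild type arrays. Of the probes, 61.8% ± 1.55 (SD, n = 3) were well above background in fat-1 blood and 60.2% ± 1.56 in wild type blood, a difference of 1.64 percentage points (two-sided exact permutation p = 0.4, where 0.1 is the smallest the design allows). Arrays correlated at 0.955 to 0.984 over probes. Wild type replicate 2 stood farthest from the rest, with a mean correlation of 0.970 to its own group. Spike-ins had a median signal of 5871 on the array of fat-1 replicate 1, against 1844 to 3008 on the other 5. No probe was annotated to the transgene, so the genotype was not checked at its transcript. The bovine gene FAT1, a cadherin given here only for its like-sounding name, had differences of 0.54 and 0.88 at 2 probes, neither past the threshold.

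The difference with the smallest adjusted p was in OAS1X, an interferon-induced oligoadenylate synthetase of the antiviral response, which rose in fat-1 blood with an adjusted p of 0.000249. The rise was at least 12.2-fold in processed intensity, with a fitted log2 difference of 5.35 ± 0.24 (SE), and 2.29 with normexp background correction, below that bound. Its probe lies on chromosome 17 at 64590856 to 64590915 and stood at -1.25 ± 0.33 (SD, n = 3) in fat-1 animals. It was not well above background in any wild type animal. GNG4, a gamma subunit of heterotrimeric G proteins, rose at least 8.27-fold, with a fitted 4.51 ± 0.41 and 1.88 with normexp, again below the bound. A second GNG4 probe rose at least 9.32-fold in processed intensity. CYB5R2, a cytochrome reductase, and SH3GL3, an endophilin of membrane curvature, were measured in all animals and rose by 2.87 ± 0.32 and 2.66 ± 0.28. CYB5R2 lies on chromosome 15 at 44263029 to 44263088 and SH3GL3 on chromosome 21 at 24248376 to 24248435.

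The other 6 genes named here for the size of the fitted rise had no signal well above background in wild type blood, so that rise and its rank are not known exactly. Among them were both carbonic anhydrases that passed, the membrane-bound CA4 (at least 3.51-fold, adjusted p = 0.0463) and the mitochondrial CA5A (at least 1.63-fold, adjusted p = 0.0123). PEX5, the import receptor of peroxisomes, rose at least 4.70-fold, but its other probe had a difference of -0.49. FRZB, a secreted Wnt antagonist, rose at least 3.85-fold, with 0.58 at its other probe. ADAMDEC1, a metalloprotease of macrophages and dendritic cells, rose at least 1.41-fold and ARHGEF28, an exchange factor of the small GTPase RhoA, at least 1.40-fold. The second CA5A probe had a difference of 0.38. With normexp background correction none of the 6 passed, with 1.09 for CA4, 1.22 for PEX5, 0.995 for FRZB, 0.56 for ADAMDEC1, 0.36 for CA5A and 0.46 for ARHGEF28, all but ADAMDEC1 below the bounds given.

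G0S2, an inhibitor of the triglyceride lipase PNPLA2, fell at least 8.76-fold at one probe in processed intensity, with a fitted difference of -4.29 ± 0.31 and an adjusted p of 0.00313. With normexp G0S2 had -1.90, a smaller fall than that bound. Its other probe fell by 3.74 ± 0.23 (adjusted p = 0.00115) and was well above background in 1 of the 3 fat-1 animals. The first of these lies on chromosome 16 at 71804334 to 71804393. IFI27, an interferon-induced protein, moved opposite to OAS1X and fell by 3.92 ± 0.32 at the probe on chromosome 21 at 59045150 to 59045209, from 0.22 ± 0.23 in wild type to -3.71 ± 0.61 in fat-1 animals. The other IFI27 probes had differences of -2.07 and -2.05, which both passed. CXCL2, a chemokine that draws neutrophils, fell by 2.93 ± 0.41.

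The feedback inhibitors of growth factor and MAP kinase signalling SPRY2 and DUSP4 fell by 1.69 ± 0.24 and 1.62 ± 0.22, with DUSP4 well above background in 1 of the 3 fat-1 animals and at -0.67 with normexp, where it did not pass. CYGB, the oxygen-binding cytoglobin, fell by 2.59 ± 0.36, and FGD5, an exchange factor of Cdc42 known from endothelium, by 2.56 ± 0.25. JUP, the plakoglobin of cell junctions, fell by 2.18 ± 0.27, with -0.63 at its other probe. HNF4A, a transcription factor of liver and gut, fell by 2.00 ± 0.23 and was well above background in 2 of the 3 fat-1 animals. The scaffold protein HOMER2 fell by 1.75 ± 0.22. The adjusted p of these 7 genes lay between 0.0126 for FGD5 and 0.0485 for SPRY2.

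**Figure D1:**
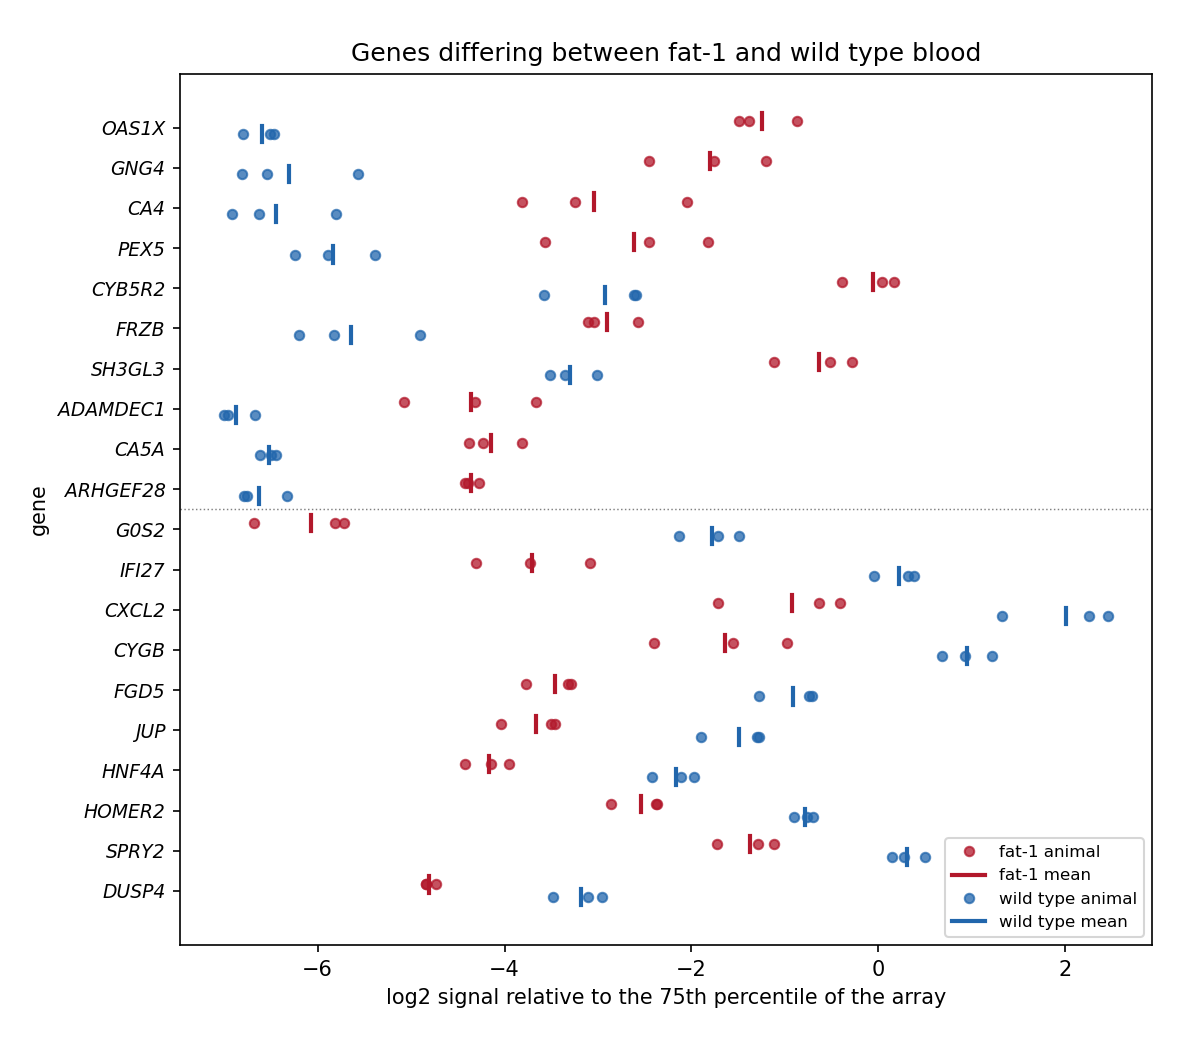
Log2 signal relative to the 75th percentile of the array (horizontal axis) for the 20 named genes (vertical axis), with points for animals and bars for group means. The groups do not overlap for any gene, as with OAS1X, at -1.25 on average in fat-1 and -6.60 in wild type blood.

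By limma, 46 probes of 26823 differed at an adjusted p under 0.05, 21 higher and 25 lower in fat-1 blood, with 26 gene symbols among them and 16 probes without one. At an unadjusted p under 0.05 there were 3437 probes, where chance gives 1341, and 1086 of these differed at least 2-fold, 584 higher and 502 lower. The animals of the groups did not overlap for 5258 probes, or 19.6%, against 10% by chance. Many calls were on dim probes, with 15 of those higher not well above background in any wild type animal and 7 of those lower in no fat-1 animal. OAS1X, GNG4, G0S2 and IFI27 passed without any 1 of the 6 arrays, with the same probes kept. The 46 probes became 8 without fat-1 replicate 1, the oldest animal and the array with the brightest spike-ins, 12 without fat-1 replicate 2 and 13 without fat-1 replicate 3. Of the 20 genes named above, 4, 6 and 6 still passed in these fits, and 11, 10 and 10 without wild type replicates 1, 2 and 3. The 1086 probes became 2368 without wild type replicate 3. The filter on dim probes was also set again on the 5 arrays left. In those fits 0, 1 and 0 probes were called higher without fat-1 replicates 1, 2 and 3. The 15 higher probes not well above background in any wild type animal, OAS1X and GNG4 among them, could not be fitted there. These counts were therefore limited in advance. With the same probes kept, 3, 5 and 5 probes were called higher without fat-1 replicates 1, 2 and 3. Nor was the first G0S2 probe, well above background in wild type animals only, fitted without a wild type array. With quantile scaling 16 probes passed, 9 of the 20 genes among them, and with normexp background correction 188, 61 higher and 127 lower, with 13 of the 20 genes. With no filter on dim probes 14 passed, with an intensity trend 143 and with array weights 2028. Of the 26 genes called, 13 had another measured probe, and OAS1X had none. Of the 16 other probes, 4 of them called too, 11 moved the same way by at least 50% as much. Variants under single probes stay possible for the rest and for calls without another probe. Each group was on a slide of its own, so slide and group cannot be told apart.

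The list of immediate-early and heat shock genes, called immediate-early for short below, was lower in fat-1 blood, with a median of -0.31. It passed camera (adjusted p = 0.000187, and adjusted p = 0.785 with an estimated correlation). Of 28 measured immediate-early and heat shock genes, 13 fell and 0 rose, adjusted over the list alone, against 0 over all probes and 13 at an unadjusted p under 0.05 in limma. The stress phosphatase subunit PPP1R15A fell by 1.90 ± 0.31, the transcription factor ATF3 by 1.54 ± 0.30, the MAP kinase phosphatase DUSP1 by 1.22 ± 0.25 and the survival gene IER3 by 1.38 ± 0.32 (p adjusted over the list alone 0.00582 to 0.0149). The other 15 did not pass, most heat shock genes and several immediate-early genes among them. Of the heat shock genes, HSPA8 had -0.16, HSPD1 0.21 and HSPH1 0.31, named after their values were seen. Without wild type replicate 3 the list's median was -0.48. The labels give neither the time from bleeding to lysis nor cell counts, to which these genes are sensitive.

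Some inflammatory cytokines and targets of NF-kB were lower, in a list whose median of -0.24 passed camera (adjusted p = 0.00265, and adjusted p = 0.785 with an estimated correlation). Of 28 measured members 9 fell and 0 rose, adjusted over the list alone, with 0 past the threshold over all probes and 10 at an unadjusted p under 0.05 in limma. The neutrophil chemokine CXCL3 fell by 3.79 ± 0.68, and the list's probe for CXCL2, which has GRO1 as its current symbol, by 2.75 ± 0.48. NFKBIA, the inhibitor that NF-kB induces against itself, fell by 1.58 ± 0.25 and the adhesion molecule ICAM1 by 1.39 ± 0.23, with -0.32 at a second ICAM1 probe (each with p adjusted over the list alone of 0.00306). The other 19 did not pass, with TNF at 0.09, CXCL8 at 0.26, CCL5 at 0.76 and RELA at -0.20, named after their values were seen. Without wild type replicate 3 the list's adjusted p was 0.0994.

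Markers of gamma-delta T cells, which make up a large part of the T cells in cattle blood, fell as a list in camera, with an adjusted p of 0.000325, and had an adjusted p = 0.840 with an estimated correlation. Their median was -1.45 over 7 measured members and -0.84 without fat-1 replicate 1. Adjusted over the list alone 5 fell and 0 rose, against 0 over all probes and 5 at an unadjusted p under 0.05 in limma. SOX13, a transcription factor of the lineage, fell by 1.5 ± 0.32, the scavenger receptor genes WC1.3 and CD163L1 by 1.52 ± 0.41 and 1.45 ± 0.51, and the receptor constant region gene TRGC6 by 1.45 ± 0.42, with 0.26 at another TRGC6 probe. The list mean was -1.44, 0.02 and -0.39 in fat-1 animals 1 to 3 and 0.42, 0.85 and 0.53 in wild type animals, relative to the mean over all animals. The fifth gene, ID3, named after its values were seen, fell by 1.18 ± 0.42. WC1.3 and TRGC6 had a p adjusted over the list alone of 0.0699 without wild type replicate 2, where CD163L1 had 0.119, and CD163L1 had 0.0595 without fat-1 replicate 1, 0.0543 after quantile scaling and 0.0539 in the authors' value table. SOX4 and GATA3 did not pass, at -0.82 and -0.53. Alpha-beta T cell and B cell markers had medians of -0.14 and -0.18, with adjusted p of 0.636 and 0.786.

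Nuclear-encoded subunits of oxidative phosphorylation fell as a list, with 57 of 62 measured members below 0 and a median of -0.26 (camera adjusted p = 0.000437, and adjusted p = 0.913 with an estimated correlation). No single member passed, over the list alone or over all probes, and 1 had an unadjusted p under 0.05 in limma. COX5A of complex IV had a difference of -0.67 and NDUFS8 of complex I one of -0.53. Camera gave 0.219 after quantile scaling, 0.220 in the authors' value table and 0.0800 without fat-1 replicate 2. The median was -0.07 after quantile scaling and in the authors' value table, and -0.155 without wild type replicate 2. The share of all measured genes below 0 was not taken, and their median was -0.08. Housekeeping genes had 16 of 21 below 0 and a median of -0.16, which was 0.03 after quantile scaling. A shift that depends on the scaling therefore cannot be told apart from a fall of these subunits.

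**Figure D2:**
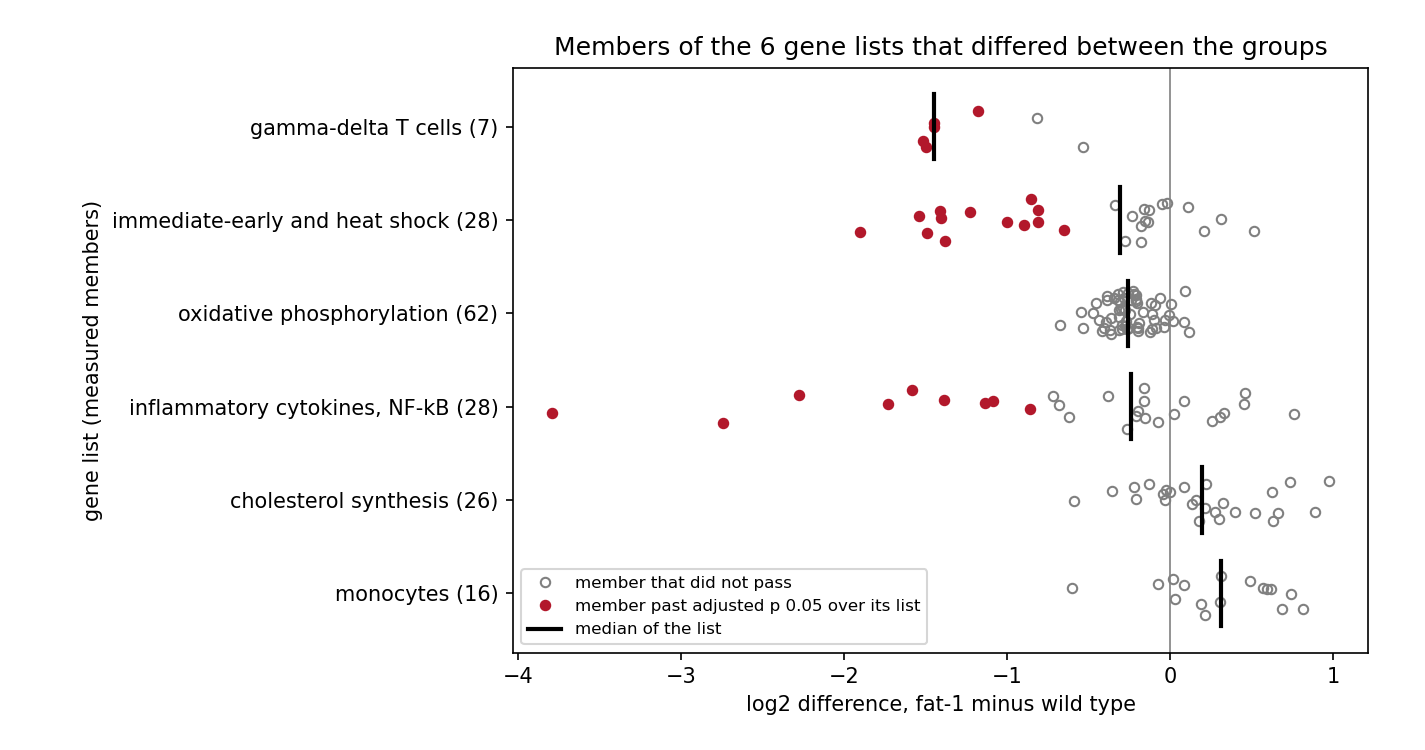
Log2 difference, fat-1 minus wild type (horizontal axis), of each measured member of the 6 lists that passed camera (vertical axis), with filled points for members past an adjusted p of 0.05 over the list alone and bars for list medians. The medians run from -1.45 for gamma-delta T cells to 0.31 for monocytes.

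Among the 7 lipid lists, cholesterol synthesis rose, with 18 of 26 measured members above 0 and a median of 0.20 (camera adjusted p = 0.00611, and adjusted p = 0.785 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, had a difference of 0.89 ± 0.23 and the sterol oxidase MSMO1 one of 0.98 ± 0.25, and both had a p of 0.0527 adjusted over the list alone. That p was below 0.05 for both genes in 7 of the alternatives, with 0.0285 after quantile scaling for example, and in 1 fit with an array left out, with 0.0263 without wild type replicate 3. In the fit to all arrays no member passed over the list alone or over all probes, and 6 had an unadjusted p under 0.05 in limma, 5 higher and 1 lower. The lower one was SREBF2, a transcription factor of the pathway named after its values were seen, at -0.59. The list had an adjusted p of 0.0521 and a median of 0.123 with the mean of all probes of a gene, and both were 0.109 without wild type replicate 3.

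In lipid uptake, storage and lipolysis 1 gene rose and 1 fell of 25 measured, adjusted over the list alone, and 1 passed over all probes. G0S2 is the one that fell. LPL, the lipase that frees fatty acids from lipoproteins, rose by 2.13 ± 0.48 (p adjusted over the list alone 0.0234). LPL had 0.0996 without fat-1 replicate 2, 0.0833 without fat-1 replicate 3, 0.0505 without wild type replicate 1 and 0.0913 without wild type replicate 3. The list's median of -0.08 and mean of -0.07 were below 0 where camera pointed up, with an adjusted p of 0.786.

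In the other 5 lipid lists no gene passed over all probes or over the list alone in limma. PUFA desaturation and elongation, the list nearest to the enzyme the transgene adds, had a median of -0.09 over 16 members, a mean of 0.02, camera pointing up and an adjusted p of 0.709, with 2 members at an unadjusted p under 0.05. Its member SCD5, a desaturase not well above background in any wild type animal, stood at least 1.36-fold higher in fat-1 blood and HSD17B12 of fatty acid elongation had a difference of 0.70. Fatty acid and triglyceride synthesis had a median of -0.03 against a mean of 0.07 and camera pointing up (adjusted p = 0.786), with 0.75 for the acyltransferase GPAM and -0.47 for the synthase FASN. Fatty acid oxidation had a median of -0.13 (adjusted p = 0.786), with -0.91 at one probe of CPT1B, which takes fatty acids into mitochondria, and 0.28 at its other probe. Cholesterol efflux and LXR targets had a median of -0.04 and a mean of -0.04 with camera pointing up (adjusted p = 0.823), with 0.58 for OSBPL1A and -0.54 for MYLIP. Eicosanoid synthesis and receptors had a median of -0.10 (adjusted p = 0.786), with -1.13 for the epoxide hydrolase EPHX2 and 1.42 for the leukotriene synthase LTC4S. Without wild type replicate 3 these 2 genes had 0.0320 and 0.0312 over the list alone. Members at an unadjusted p under 0.05 numbered 1, 3, 2 and 4 in these 4 lists.

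Monocyte markers rose as a list, with 14 of 16 above 0, a median of 0.31 and a camera adjusted p of 0.0282, and it had an adjusted p = 0.785 with an estimated correlation. No member passed, over the list alone or over all probes, and 1 had an unadjusted p under 0.05 in limma. The chemokine receptor CX3CR1 had a difference of 0.69 and the protease inhibitor CST3 one of -0.60. The list had an adjusted p of 0.0521 with the mean of all probes of a gene, 0.0537 without fat-1 replicate 1, 0.101 without fat-1 replicate 2 and 0.234 without wild type replicate 3, where its median was 0.19.

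Of the 30 lists, 6 passed camera, 4 lower and 2 higher. With an estimated correlation 0 passed and 1 had an unadjusted p under 0.05, and with fry 0 passed, 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0692 for the inflammatory list. By fry's test for change in either direction, 7 passed. Of the lists that passed camera, these included the immediate-early, inflammatory and cholesterol synthesis lists. In that test gamma-delta T cells had an adjusted p of 0.146, oxidative phosphorylation 0.203 and monocytes 0.390. The rest were interferon-stimulated genes, lipid uptake, NK and cytotoxic cells and platelets, which did not pass camera. Of the 10 ways to split the arrays into 3 and 3, the real one included, 6 gave 6 or more lists. The 6 lists became 3 without wild type replicate 3.

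**Figure D3:**
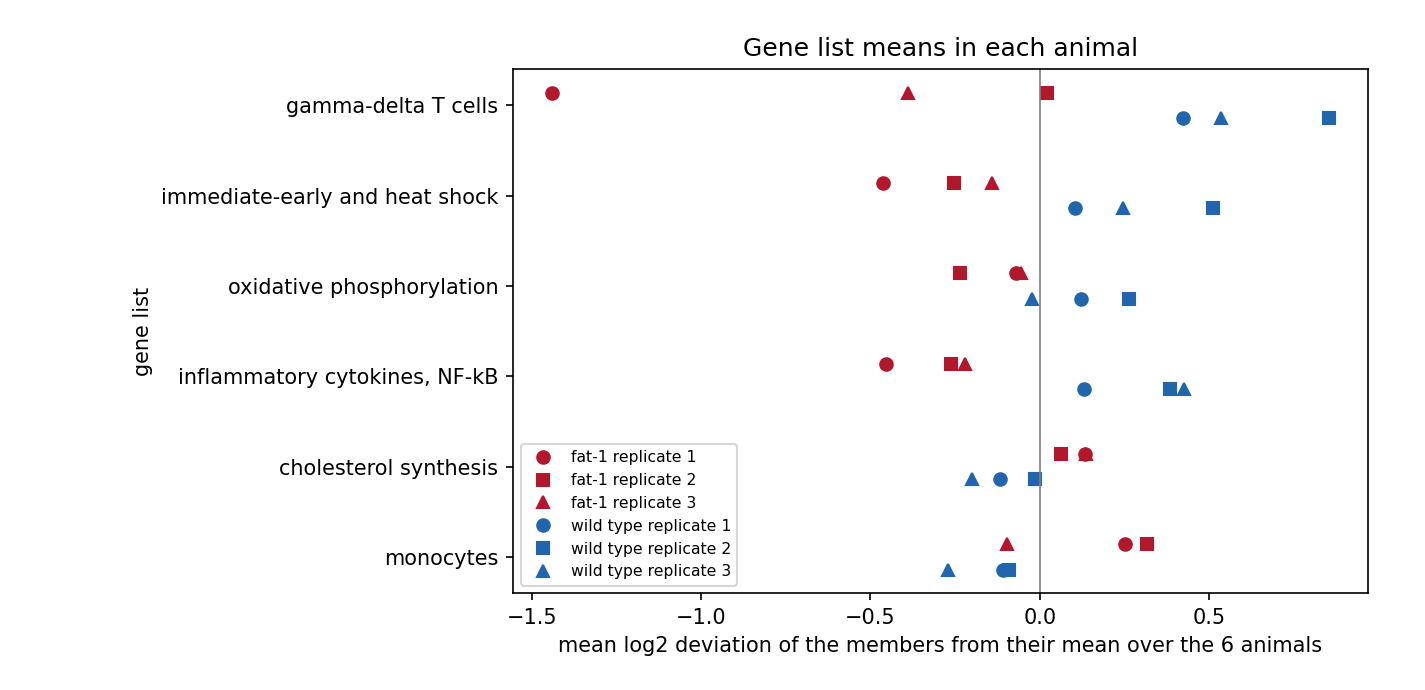
Mean log2 deviation of a list's members from their mean over the 6 animals (horizontal axis), for the 6 lists that passed camera (vertical axis), with 1 point per animal and shapes for replicate numbers. In the immediate-early list the fat-1 animals sit between -0.46 and -0.14 and the wild type animals between 0.10 and 0.51.

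Interferon-stimulated genes did not pass as a list, with a median of 0.05 over 40 members and an adjusted p of 0.0991, which was 0.0184 without fat-1 replicate 1, 0.0227 without wild type replicate 1 and 0.0473 with normexp. Adjusted over the list alone 2 rose and 1 fell, and 2 passed over all probes, OAS1X and IFI27. The other is IFIH1, a sensor of viral RNA named after its values were seen, which rose by 2.36 ± 0.45. NK and cytotoxic cell markers had a median of 0.16 (adjusted p = 0.309, and 0.0424 without fat-1 replicate 1), with 4 that rose and 2 that fell, adjusted over the list alone, 0 over all probes and 8 at an unadjusted p under 0.05 in limma. The lectin-like receptors KLRC1 and KLRB1 went opposite ways, KLRC1 rising by 1.99 ± 0.44 and KLRB1 falling by 1.35 ± 0.24.

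Platelet markers had a median of 0.40 (adjusted p = 0.327). Adjusted over the list alone 3 of the 17 fell, 0 passed over all probes and 6 had an unadjusted p under 0.05. The matrix genes LTBP1 and THBS1 fell by 0.95 ± 0.21 and 1.12 ± 0.26, and both had a p adjusted over the list alone of 0.0620 without fat-1 replicate 1 and 0.0677 without fat-1 replicate 3. PDGFA, a growth factor of platelet granules named after its values were seen, fell by 1.64 ± 0.40. Erythroid markers had a median of 0.02 (adjusted p = 0.786), with 2 of 23 that fell over the list alone, 0 over all probes and 6 at an unadjusted p under 0.05. Without wild type replicate 2 their median was 0.344, higher in fat-1 blood, with a camera adjusted p of 0.00646. The anion exchanger SLC4A1 fell at least 1.46-fold. SLC4A1 had 0.0556, 0.0534 and 0.0608 over the list alone without fat-1 replicate 1, wild type replicate 1 and wild type replicate 3, and 0.0813 with normexp. Imprinted genes had a median of -0.07 (adjusted p = 0.786), with 1 that rose and 1 that fell over the list alone, 0 over all probes and 5 at an unadjusted p under 0.05. NAP1L5 rose by 1.16 ± 0.27 and PHLDA2 fell by 1.23 ± 0.26. Without fat-1 replicates 1, 2 and 3 or wild type replicate 2, PHLDA2 had 0.0610, 0.0549, 0.0545 and 0.0579 over the list alone and NAP1L5 had 0.0610, 0.0890, 0.0567 and 0.0579.

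In the remaining lists no member passed in limma, and none passed camera. Neutrophil markers had a median of 0.05 (adjusted p = 0.709), and they passed without wild type replicate 2, with a median of 0.28 and an adjusted p of 0.0181. The Toll-like receptor pathway had a median of 0.05 and class I antigen presentation one of -0.24 (both 0.309). Eosinophil markers had 0.18 (adjusted p = 0.354) and plasma cell markers -0.18 (adjusted p = 0.636). Proliferation genes had -0.14 and basophil and mast cell markers -0.26 (both 0.709). Dendritic cell markers had -0.19 and class II antigen presentation -0.24 (both 0.786), the latter with a mean of 0.13. Antioxidant genes had a median of -0.02 against a mean of 0.02 and camera pointing up (adjusted p = 0.751). Members at an unadjusted p under 0.05 were at most 4, in the Toll-like receptor pathway.

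Housekeeping genes had a median of -0.16 over 21 members (adjusted p = 0.709), which was 0.03 both after quantile scaling and in the authors' value table. PPIA had a difference of -0.26 and ACTB one of -0.21. GAPDH had -0.14, which turned to 0.08 after quantile scaling and in the authors' value table and to 0.02 without wild type replicate 2. The median over all measured genes was -0.08.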

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

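The alternatives of this part were all planned, so no test of this part was chosen after the result was seen, but 3 details of the settings were: members of lists were matched by current symbol first, array weights were estimated gene by gene because the default estimate did not converge, giving wild type replicate 1 a weight of 238, and probes were kept the same when an array was left out. The comparisons, the genes of each list and the alternatives were fixed before the data were examined. The slide as a block was not run, because each slide held 1 group.

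The 46 probes that differed became 16 with quantile scaling, 16 in the authors' value table, 188 with normexp, 14 with no filter on dim probes, 81 with probes well above background on all arrays of a group, 143 with an intensity trend, 2028 with array weights and 134 at an adjusted p under 0.1. Leaving out an array gave 8 (fat-1 replicate 1) to 57 (wild type replicate 1). With the filter set again on the 5 arrays left, the form tried first, it gave 4 to 66. Of the 46 probes, 16 remained with quantile scaling, 30 with normexp, 12 with no filter and 38 with the trend. The split of the 1086 probes at least 2-fold different, 584 higher and 502 lower, became 129 and 232 of 361 with normexp. There were 1779 such probes with no filter, 661 with probes well above background on all 6 arrays, and 828 to 2368 (without wild type replicates 2 and 3) with an array left out. The cause was not tested, apart from the number of probes fitted under each filter.

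The 6 lists became 0 with an estimated correlation and 0 with fry, and 3 (without wild type replicate 3) to 8 (without wild type replicate 2) with an array left out. The immediate-early list and gamma-delta T cell markers passed camera in every other setting, at adjusted p up to 0.0227 and 0.0296. With an estimated correlation and with fry no call remained for immediate-early genes (median -0.31), inflammatory genes (-0.24), oxidative phosphorylation (-0.26) or cholesterol synthesis (0.20), which also lost its call at 0.123 with the mean of all probes of a gene. Quantile scaling and the authors' value table moved antioxidant genes to 0.158 and 0.156, cholesterol efflux to 0.119 and 0.122, eicosanoid genes to -0.0135 and -0.0139, fatty acid oxidation to -0.00854 and -0.00884, housekeeping genes to 0.0322 and 0.0335, oxidative phosphorylation to -0.0728 and -0.0726 (call lost), PUFA genes to 0.0778 and 0.0790 and Toll-like receptor genes to 0.203 and 0.204. Interferon-stimulated genes gained a call with normexp, at 0.0254. Array weights moved eicosanoid genes to 0.0112, PUFA genes to 0.0526 and Toll-like receptor genes to -0.0241, and B cells, NK cells and erythroid cells gained a call, at medians of -0.567, 0.455 and 0.305 and adjusted p of 0.0137, 0.0374 and 0.0477. HMGCS1 and MSMO1 gained one over the list alone with quantile scaling, the value table, normexp, both stricter filters, the trend and array weights, and EPHX2, LTC4S, GPAM, CPT1B, SCD5 and HSD17B12 with array weights alone among these. With an array left out, medians ran from 0.109 to 0.253 for cholesterol synthesis, -0.170 to -0.0376 for eicosanoid genes, -1.60 to -0.837 for gamma-delta T cells, -0.480 to -0.315 for immediate-early genes, 0.190 to 0.413 for monocytes, -0.202 to 0.135 for fatty acid and triglyceride synthesis, -0.287 to 0.0207 for fatty acid oxidation, -0.301 to -0.0606 for housekeeping genes, -0.346 to -0.232 for inflammatory genes, 0.00341 to 0.113 for interferon-stimulated genes, -0.0852 to 0.103 for lipid uptake, -0.344 to -0.155 for oxidative phosphorylation, -0.149 to 0.0688 for PUFA genes and -0.0765 to 0.124 for Toll-like receptor genes. The difference in the share of probes well above background ran from 0.744 to 2.35 with an array left out. All 20 named genes kept their direction in every setting that measured them. OAS1X, GNG4, G0S2 and IFI27 also passed in each, with the same probes kept when an array was left out. GAPDH reversed, to 0.0836 with quantile scaling, 0.0771 in the value table and 0.0181 without wild type replicate 2, with -0.318 without wild type replicate 3. Signal over background limits the size of calls where the dimmer group was not well above it on any array, at 15 of the 21 probes higher and 7 of the 25 lower.

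The replicate numbers were not shown to pair animals: deviations of animals with the same number correlated at 0.117, 0.185 and 0.00583, and fat-1 replicate 3 matched wild type replicate 1 best, at 0.0768. With the replicate block 109 probes passed, 44 of them among the 46.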

Other observations

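Of the tests below, those on chance for the 2 counts of probes, on monocyte and neutrophil content, on handling time, on WC1 copies and on the share of lymphocytes were chosen after the result was seen, as were the genes of the next 2 paragraphs.

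Further probes described as WC1 or lying on the same chromosome stretch as TRGC6 were among those past the threshold. A probe described as a WC1 isolate, at 9782347 to 9782497 on chromosome 5, fell by 1.84 ± 0.25 (adjusted p = 0.0463). On chromosome 4, where the TRGC6 probe starts at 52078171, probes at 52175886 and 52188989 fell as well. The first fell at least 2.12-fold and the second had a difference of -2.04. Both are described as the same unnamed RNA locus and are not assigned to the receptor gamma genes. The other 3 WC1.3 probes did not pass, with -1.94, -1.69 and at least 2.51-fold lower, and adjusted p of 0.0515, 0.248 and 0.0525. The 5 other CD163L1 probes lay between -1.41 and -1.59. A second cytoglobin probe, at 56892053 on chromosome 19, fell by 2.76.

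LOC782922, described as a prostaglandin F synthase, rose at least 4.0-fold (adjusted p = 0.0269), outside the eicosanoid list. The beta-defensin gene EBD rose by 2.22 ± 0.26, and CDO1, the cysteine dioxygenase of taurine synthesis, at least 1.99-fold. A fragment annotated to the transporter ABCC4 fell by 3.54 ± 0.49. In the interferon list OAS1Y and OAS1Z, relatives of OAS1X, had differences of -0.19 and -0.32. EGR1 and FOS of the immediate-early list fell by 1.41 ± 0.44 and 1.40 ± 0.48 over the list alone, and so did TNFAIP3, by 1.73 ± 0.32, and IL1A, by 2.27 ± 0.66, of the inflammatory list.

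The first pattern is the 46 probes that differed, where 1 of the 10 splits of the arrays gave as many, the real one, and the highest of the others gave 1. For the 1086 probes it was also 1, with 736 as the highest other. The splits are too few for a share under 0.05. For a local defect of a slide, 27.5% of 10000 random sets lay as close together on the array, above the bound of 5% set beforehand. The median distance to the nearest was 14.2 spots, against 15.4 in random sets. A defect stays open for some of the probes, since a median over all 46 cannot exclude one under a few of them. A sequence variant under single probes may account for some calls. Of the 26 genes called, 13 had another measured probe, and OAS1X had none. Among these 16 other probes, 4 of them called too, a share of 0.688 (exact 95% interval 0.413 to 0.890) moved the same way by at least 50% as much. The slide cannot be told apart from the group, with spike-ins differing by 0.21 between slides at an SD of 0.61. The bright spike-ins of fat-1 replicate 1 add to that SD (5871, against 1844 to 3008).

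The second pattern is the lower level of the immediate-early list, with its heat shock genes, and of the inflammatory list. Wild type replicate 2 alone is argued against, since without it the plain median over both lists was -0.31 ± 0.14. Relative to the median of all genes it was -0.29 without that array and -0.19 ± 0.13 with all arrays. Here and for the third pattern, the value after ± is the SE over animals of the group difference in the list's mean. It stands in for the spread of the median, which was not estimated. Fewer monocytes are argued against only weakly by their markers, 0.39 ± 0.14 above the median of all genes. The monocyte list did not pass camera with an estimated correlation (adjusted p = 0.785) or without wild type replicate 3 (adjusted p = 0.234). Fewer neutrophils stay open, with 0.13 ± 0.35. The time from bleeding to lysis may differ between the groups: the means of the immediate-early list left a gap of 0.25 between the lowest wild type and the highest fat-1 animal, which either handling or the transgene could give, and the labels hold no times. For the number of lists that passed camera, 6 of the 10 splits gave as many as the real one (6 lists) or more, itself included. The highest other gave 10. The number of lists therefore does not set the real split apart from arbitrary ones, as predicted if it arose by chance. The splits are also too few for a share under 0.05.

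The third pattern is the lower level of gamma-delta T cell markers. Copies and variants of the WC1 family as the whole cause are argued against, because the 5 members outside it lay -1.098 ± 0.40 from the median of all genes, though GATA3, ID3 and SOX4 are also known from other lymphocytes. Wild type replicate 2 alone and the age of fat-1 replicate 1 are argued against by -1.22 ± 0.44 and -0.78 ± 0.24 without these animals. Both values are again relative to the median of all genes. A lower share of all lymphocytes as the whole cause is argued against by alpha-beta T cell and B cell markers. They lay at -0.0627 ± 0.21 and -0.10 ± 0.28 relative to the median of all genes. With array weights, though, B cell markers fell, with a plain median of -0.567 beside -1.15 for gamma-delta T cells and -0.09 for all genes. Those weights were highest for wild type replicate 1, at 5.71, and in the unweighted fit without that array the plain B cell median was 0.134. A smaller share of gamma-delta T cells in fat-1 blood is a hypothesis that stays open, as do the slide and differences between the few animals.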
